A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

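The series holds 24 RNA-seq libraries of budding yeast: 18 haploid libraries from 6 strains and 6 diploid libraries from 2 strains, 3 replicates each. Per the submitters' processing notes, cells were grown in rich glucose medium at 25 °C to log phase and lysed with glass beads. Poly(A) RNA libraries were made from 500 ng of total RNA with 10 cycles of PCR by a stranded (dUTP) method and read as single reads of 50 bases on an Illumina HiSeq instrument. The notes name bcl2fastq 2.20.0.422, FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1 and DESeq2 1.28.0, with genome build R64. The counting tool, its annotation and its strand setting are not given in the sources used here, so values of genes that share reads with a paralogue or overlap a gene on the other strand are uncertain. The reads themselves were not used here.

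The values analysed are signal (DESeq2-normalised counts) as deposited by the authors in 2 tables, 5843 genes for the haploid libraries and 5730 for the diploid libraries. Within each library the values were whole multiples of a single step: 100% of them gave whole reads within a tolerance of 0.001 reads. The reciprocals of those steps equalled median-of-ratios size factors computed from the recovered reads, with a largest relative difference of 4.44e-15 in the haploid and 3.33e-15 in the diploid table. The 2 tables were normalised separately, so levels were not tested across ploidy. Depth was taken as the sum of recovered reads. No library repeated another of its strain: the chi-square per gene between replicates was between 4.41 and 187.

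All 24 columns were assigned to a strain and a replicate from the labels, and 0 columns were left unused. The diploid table heads 3 of its columns N19_Ca, a name no label explains. They were taken as N2/Ca because the labels give 2 diploid strains and only N2/Ca holds Ca. The haploid table also holds entries for introduced actin genes named N2, Ca, Sc[At], Sc[Ca] and Sc[Sp], and the diploid table for Sc[Ca], N2 and Ca. The names are used here as labels only.

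Genes were matched to the R64 annotation, 5758 by locus tag and 79 by symbol, and 3 of 5840 found no match. GC content and gene length came from the same genome sequence, for 99.98% of the tested haploid genes. Genes with a mean of at least 10 over the libraries of a table were tested: 5808 haploid and 5727 diploid genes. The test was limma 3.58.1 with a mean-variance trend on log2(value + 1), with all 18 haploid libraries in a single fit and the 6 diploid libraries in another, and Benjamini-Hochberg adjusted p under 0.05. A fold on the log2(value + 1) scale understates the change of genes with few reads. In the text, a gene rose or fell only if it passed this test, or, for Sc[Ca] where the 6-library fit is named, the same test in that fit. Errors after ± are standard deviations over 3 libraries, and SE is the standard error of the fitted log2 fold.

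There were 8 comparisons: 5 haploid strains against ScNI, N2/Ca against Sc/Sc, Ca against N2 and Ca against Sc[Ca], with an F test of any difference among the 6 haploid strains. The comparisons, the test, the thresholds, the gene lists, the named-gene rule and the first set of other settings (given last) were set before the data were examined. What the replicates are, separate cultures or separate clones, is not given in the sources used here, so a p value measures spread between these samples. In 14 of 18 haploid and 2 of 6 diploid libraries the best correlated library of the other strains carried the same replicate number. The lowest correlation between same-numbered libraries, after removing strain means, was 0.50 for Sc[Ca], 0.39 for Sc[Sp], 0.40 for Sc[At] and 0.31 for N2, each against ScNI. It was 0.06 for Ca, −0.07 for N2/Ca, −0.31 for Ca against N2 and 0.08 for Ca against Sc[Ca]. By that check, which takes the lowest value, the replicate numbers pair libraries throughout in the first 4 comparisons only. Replicate 2 still correlated at 0.51 for Ca, 0.69 for Ca against N2 and 0.52 for Ca against Sc[Ca]. The numbers thus pair haploid libraries by mating type, as described next, and a pairing beyond that is not shown. The main test did not use the pairing, and a replicate block was run as an alternative.

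Mating-type genes differed between replicates. In replicate 2 of every haploid strain, STE3 was at 6546 to 9169 normalised counts against 34.8 to 202 in the other 12 haploid libraries, and MF(ALPHA)1 at 10366 to 25872 against 0 to 11.6. STE2 was at 77.8 to 278 in those 6 libraries against 6021 to 17875, MFA1 at 3.84 to 62.9 against 671 to 1288, and BAR1 at 107 to 244 against 1093 to 4068. Replicate 2 of each haploid strain therefore showed the MATalpha pattern and the others the MATa pattern. The 2 patterns argue against replicate 2 being a further culture of the clone used for the other replicates of its strain. Because every haploid strain has the same make-up, strain means are balanced for mating type. Settings that leave out part of the libraries of a strain can break that balance.

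Genes named in the text follow a fixed rule: ACT1; the 10 higher and 10 lower genes with the largest fold in each comparison among those that passed, with a mean of at least 50 over both groups and no overlap between the 2 groups of libraries; and for each list up to 4 members that passed, largest fold first. Dubious and overlapping reading frames and Ty elements were kept out of the second part. ACT1 was kept out of the lists. For the fit of the 6 Sc[Ca] and ScNI libraries, the rule was applied to its own calls. Any other gene is said to have been chosen after its values were seen.

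The 33 lists were written from general knowledge of the genes. Lists on the cytoskeleton and its folding were actin-filament binding and monomer-binding proteins; Arp2/3 complex and its activators; endocytic coat and patch module; formins, actin cables and polarity; septins and contractile ring; CCT chaperonin and prefoldin; tubulins and microtubule proteins. Lists on stress and growth were Hsf1 and cytosolic chaperones, cell wall integrity pathway targets, Msn2/4 general stress genes, ribosome biogenesis, cytosolic ribosomal proteins, and ER folding and unfolded protein response. Lists on metabolism were glycolysis and fermentation, respiratory chain and TCA cycle, glucose-repressed genes, iron regulon, phosphate regulon, ergosterol synthesis, amino acid synthesis (Gcn4 targets), and sulfur and methionine metabolism. The rest were histones, G1/S cyclins and MBF/SBF targets, G2/M genes, pheromone response, DNA damage response, MATa-specific, MATalpha-specific and haploid-specific genes, meiosis and sporulation genes, selection and auxotrophy markers, and mitochondrially encoded genes. Also tested and counted in the totals was 1 further list that is not reported here. Ribosomal proteins were taken by symbol: RPL or RPS with a number and an optional A or B, or RPP0 to RPP2. That rule also admits RPP1, a subunit of RNase P and not of the ribosome. Of the 8 mitochondrially encoded genes, 0 were measured, so 32 lists were tested. Symbols without a match included GMF1, FKS2, ARN3 and CTH2, which the tables hold as AIM7, GSC2, SIT1 and TIS11, and HIS3 and IME4. LSO1, FIG1, PRM6, MFA1, AGA2 and MF(ALPHA)1 are absent from the diploid table.

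Lists were tested with camera at its preset correlation of 0.01, with adjusted p under 0.05 over the lists of a comparison. Camera with the correlation estimated from the data, over all libraries of the fit, and fry were run as alternatives. List counts are given from the whole-genome adjustment and, in brackets, with p adjusted over the list alone. Overlaps of calls between strains that share ScNI were set beside the overlap of independent lists of the same size, and covariances of folds beside 20 simulations in which the strains share controls and nothing else and the spread is that of the main test, replicate numbers and mating types included. Overlaps of N2 with Ca and of N2/Ca with haploids were also counted off chromosomes VI and XIII, which was added after the data were seen. The 3 ScNI libraries are too few to be split between comparisons. Regrouping was done by all 10 splits of 3 against 3 libraries, and for the F test by 100 random regroupings and, added after the data were seen, 100 regroupings within replicate numbers.

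In a self-test, counts were drawn from negative binomial distributions with the means and dispersions of the data, and 200 genes were given a known fold. In Sc[Sp] against ScNI, limma recovered 34.3% of the genes at log2 0.5, 85.1% at 1 and 100% at 2, with 2.67% false calls. In N2/Ca against Sc/Sc it recovered 16.4%, 92.5% and 100%, with 7.95% false calls. These drawn libraries lack any structure between libraries, such as a whole chromosome that differs.

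Other settings fixed in advance were a pseudocount of 5 or 0.5, no filter, a mean of at least 100, TMM factors, a replicate block, edgeR on recovered reads, limma without trend, each library left out in turn, a fit of only the 6 libraries compared, and adjusted p under 0.01 for overlaps. Settings added after the data were seen were DESeq2 on recovered reads, chromosome medians subtracted in each library, a mating-type covariate, the N2 and Ca libraries left out of the fit, Ca replicates 1 and 2 left out, Ca replicate 3 and N2 replicate 1 left out, and edgeR and DESeq2 on the 6 libraries of Sc[Ca] and ScNI. A group of 33 proteasome subunit genes was also formed after the data were seen and is described by counts and medians only. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.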

Results

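Poly(A) RNA was sequenced from 8 yeast strains in log phase at 25 °C, 3 libraries each. The haploid strains were the wild type ScNI and Ca, N2, Sc[At], Sc[Ca] and Sc[Sp], described by the submitters as having different actins. The diploids were N2/Ca and the wild type Sc/Sc. Depth was 10228523 to 15403081 reads in the haploid and 12128284 to 15134814 in the diploid libraries, and 5808 haploid and 5727 diploid genes were tested. The haploid and diploid tables were normalised separately, so levels are compared only within a ploidy.

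ACT1, the only actin gene of wild-type yeast (R64, chromosome VI:53260–54696, minus strand, exons 54687–54696 and 53260–54377), fell to near 0 in 3 haploid strains. Its mean was 18498 ± 87.3 normalised counts in ScNI (± SD, n = 3), 145.9 ± 36.2 in Sc[Ca], 20.9 ± 11.1 in Sc[Sp] and 55.9 ± 21.1 in Sc[At]. In their place the introduced genes stood at 21983 ± 429 in Sc[Ca], 17413 ± 1379 in Sc[Sp] and 18930 ± 553 in Sc[At]. The changes of ACT1 were log2 −7.01 (SE 0.37, limma adjusted p = 5.1e-08), −9.87 (3.5e-10) and −8.43 (3.5e-09).

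ACT1 did not pass in N2 or Ca. It was at 13450.0 ± 2614 in N2 (log2 −0.48, SE 0.37, limma adjusted p = 0.36) and 12798 ± 3629 in Ca (−0.58, SE 0.37, 0.25). The call depends on the setting, since ACT1 lies on chromosome VI, which is raised in these strains. With chromosome medians subtracted in each library, a setting added after the data were seen, ACT1 fell by log2 1.21 in N2 (limma adjusted p = 0.021) and 1.12 in Ca (0.026). It also passed in the 6 libraries of N2 and ScNI alone (−0.48, limma adjusted p = 0.044), but not in those of Ca and ScNI (−0.58, 0.14). The introduced N2 gene was at 20971 ± 4087 in N2 and the introduced Ca gene at 14462 ± 4149 in Ca. In the diploid N2/Ca, ACT1 fell from 24193 ± 2532 in Sc/Sc to 14197 ± 1474 (log2 −0.77, SE 0.13, limma adjusted p = 0.0085). Left out in turn, N2/Ca replicates 2 and 3 took that p to 0.052 and 0.050, with log2 −0.74 and −0.71. In N2/Ca the N2 gene was at 7071 ± 2708 and the Ca gene at 11168 ± 820. Without any introduced gene, ScNI still gave 214.7 ± 16.4 for the N2 gene, 33.5 ± 18.2 for the Ca gene and 29.6 ± 5.70 for the Sc[Ca] gene, but 0 reads for Sc[Sp]. ACT1 was 0.641 ± 0.00747 of the N2 gene in the 3 N2 libraries and 0.886 ± 0.00414 of the Ca gene in the 3 Ca libraries. How reads shared between ACT1 and an introduced gene were counted is not given in the sources used here.

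**Figure D1:**
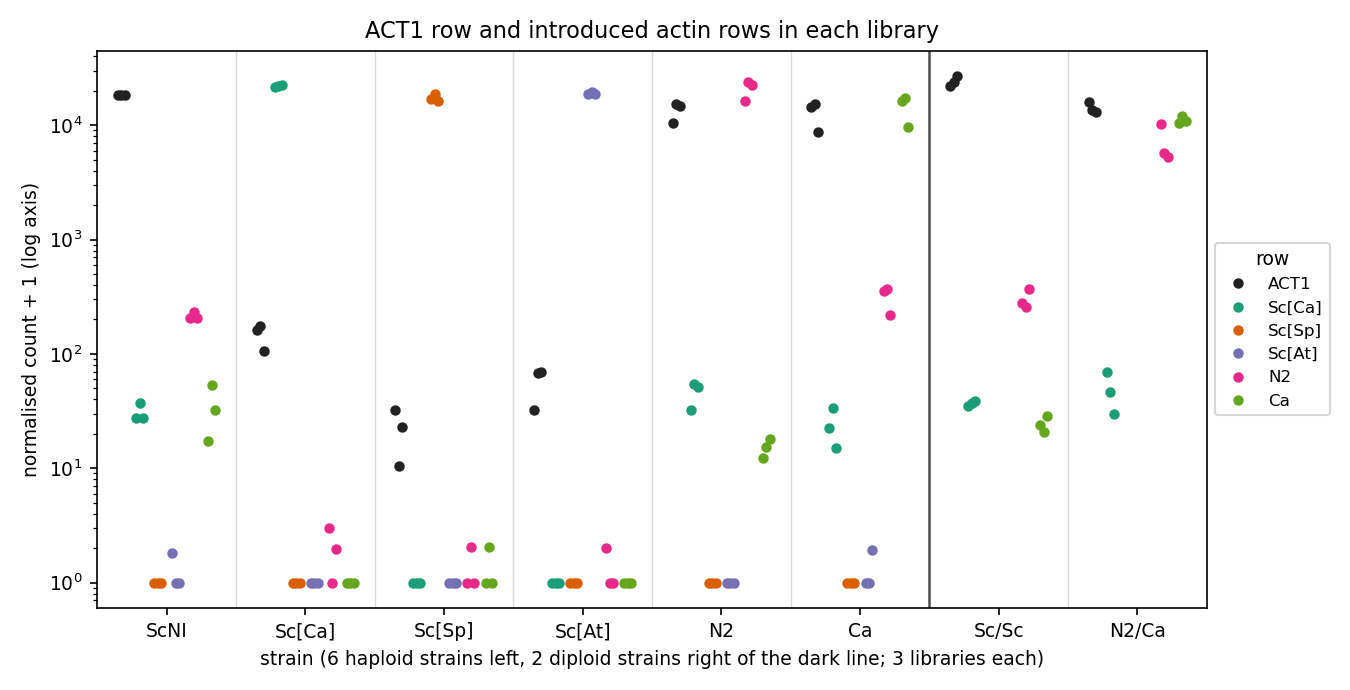
Normalised counts of ACT1 and of the introduced actin genes in every strain, on a log axis of count + 1; each point is a library, 3 per strain, with haploid strains left and diploid strains right of the dark line. ACT1 averages 18498 in ScNI and 20.9 in Sc[Sp].

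Whole chromosomes VI and XIII were raised in N2 and Ca libraries. In N2 replicates 1, 2 and 3 the median gene of chromosome VI lay at log2 0.51, 0.94 and 0.91 against ScNI, and that of XIII at 0.54, 0.98 and 0.96. In Ca replicates 1 and 2 the medians were 0.90 and 0.89 for VI and 0.92 and 0.95 for XIII, while Ca replicate 3 had 0.06 and −0.00. Chromosome XI was at 0.57 in Ca replicate 1 alone. N2/Ca replicate 1 had 0.44 for VI and 0.49 for XIII against Sc/Sc, and the other N2/Ca libraries were between −0.01 and 0.03. Strain means were 0.79 ± 0.24 (VI) and 0.83 ± 0.25 (XIII) in N2, 0.61 ± 0.48 and 0.62 ± 0.54 in Ca, and 0.14 ± 0.25 and 0.18 ± 0.26 in N2/Ca (n = 3). In the libraries other than wild type, the 251 medians of the other chromosomes, XI of Ca replicate 1 left out, lay between −0.14 and 0.18. In ScNI, Sc[Ca], Sc[Sp] and Sc[At] the medians of VI and XIII lay between −0.02 and 0.10. The libraries of N2, Ca and N2/Ca therefore differ within a strain, and genes of VI and XIII are named with their chromosome.

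**Figure D2:**
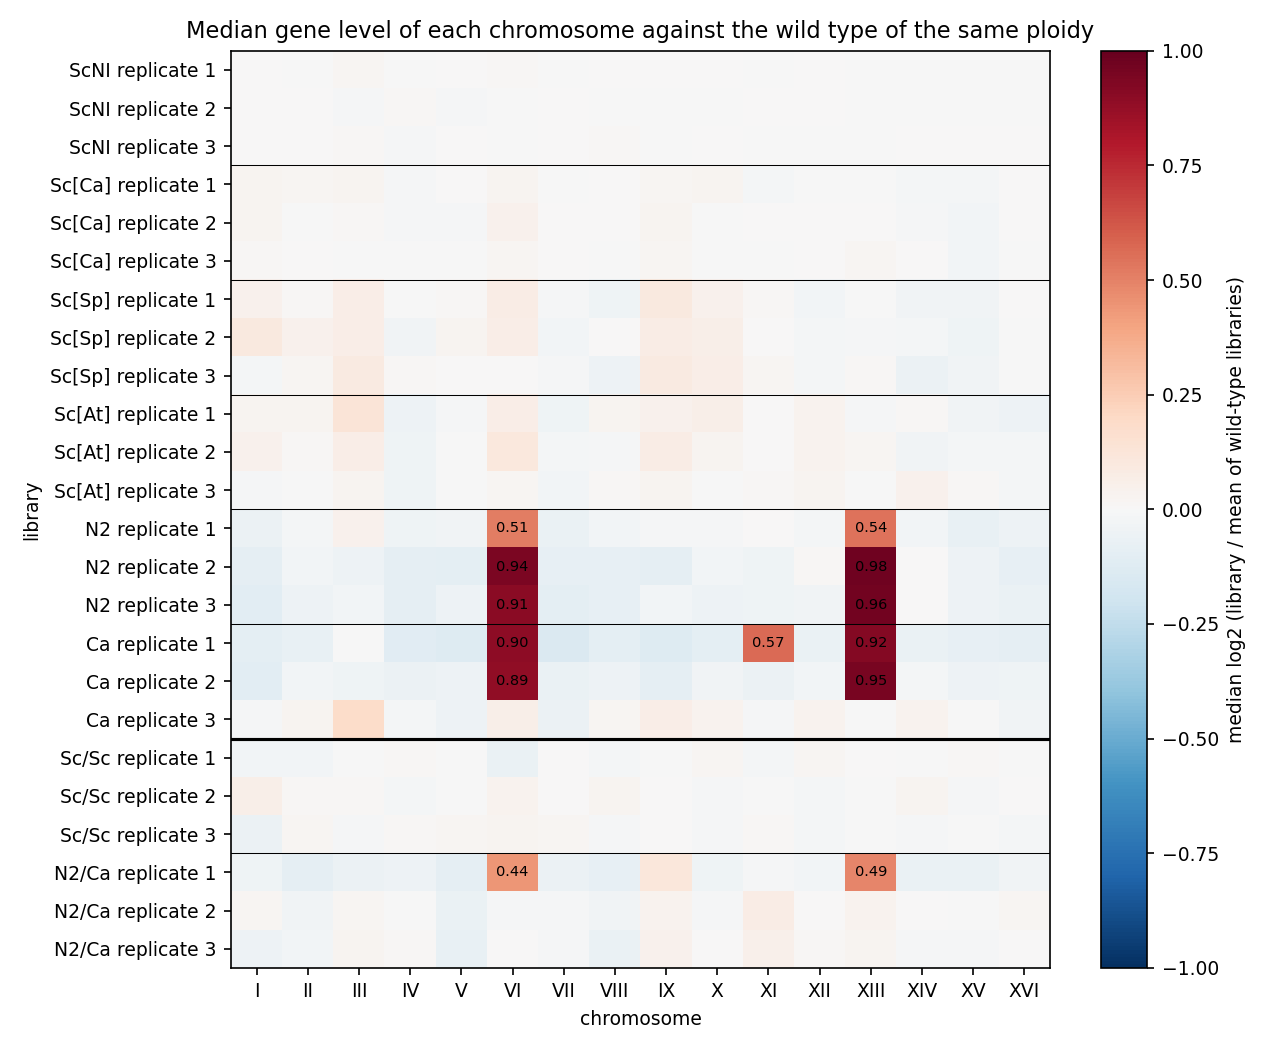
Median log2 difference of the genes of each chromosome (columns) in each of 24 libraries (lines) from the mean of the wild-type libraries of the same ploidy. Printed values mark chromosomes VI and XIII of N2, of Ca replicates 1 and 2 and of N2/Ca replicate 1. They reach 0.98 in N2 replicate 2, and XI of Ca replicate 1 is marked at 0.57.

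Among the 6 haploid strains 3517 of 5808 genes differed (limma F test; edgeR 3541, DESeq2 4121). The same 3 wild-type libraries are the reference of 5 comparisons, and because the origin of the replicates is not given, each p measures spread between these samples. With an estimated correlation camera called 0 of 32 lists in each of the 8 comparisons (limma, with 0 to 4 at unadjusted p below 0.05), so every camera call rests on the preset correlation.

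Sc[Ca] was closest to the wild type: in the main test 1 of 5808 genes passed, ACT1 (0 higher, 1 lower; limma). The small changes given next, spread over growth and stress genes, passed in an alternative fit and not in the main test. In a fit of its 3 libraries and the 3 of ScNI alone, ribosome biogenesis genes fell in 35 of 38 members (median log2 −0.39), among them the nucleolar gene NSR1 from 7315 ± 654 to 4330 ± 209 (log2 −0.75, SE 0.06, limma adjusted p = 0.00036) and the helicase gene DBP2 (−0.72, SE 0.05, 0.00026). Msn2/4 general stress genes rose in 21 of 26, led by GAD1 (0.74, SE 0.07) and the trehalose synthase subunit TSL1 (0.68, SE 0.08). The small heat shock protein gene HSP26 rose most, from 222 ± 48.6 to 485 ± 81.5 (1.13, SE 0.17), and the iron-mannoprotein genes FIT2 and FIT3 fell by log2 1.08 and 1.01 (SE 0.20 and 0.15). Of 34 actin-binding genes 14 rose slightly, with LAS17, the yeast WASP, at 0.27 (SE 0.08) and its partner VRP1 at 0.34 (SE 0.07).

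That 6-library fit passed 961 of 5777 genes (456 higher, 505 lower; limma), with a median size of log2 0.27 and 5 genes beyond 2-fold; edgeR passed 891 and DESeq2 976. The fit of all 18 libraries, set as the main test, passed a single gene, ACT1 (0 higher, 1 lower; edgeR 1, DESeq2 2, 234 genes at unadjusted p below 0.05), and with the N2 and Ca libraries left out, a setting added after the data were seen, it passed 4. The 6-library fit takes its error from Sc[Ca] and ScNI alone, where that of the main test is pooled over 6 strains. Gene lists of the other comparisons were described by the main test, so the counts of this fit cannot be set beside theirs. The choice of fit matters there too: between Ca and N2 the main test passed 30 genes and the fit of their 6 libraries 0 (limma). Within the 6-library fit the respiratory chain and TCA cycle rose in 21 members and fell in 2 of 43 (27 and 3 with p adjusted over the list alone). The endocytic coat and patch module rose in 13 of 29 (14) and the Arp2/3 complex and its activators in 6 of 15 (7). Hsf1 and cytosolic chaperones rose in 11 and fell in 1 of 26 (12 and 3). Lower were 28 of 138 cytosolic ribosomal proteins with 1 higher (40 and 1 adjusted over the list alone), 11 of 22 iron regulon genes (11, with 1 higher), 7 of 25 ergosterol synthesis genes (9) and 6 of 10 histones (7). Adjusted over the list alone the ribosome biogenesis list had 38 lower, the Msn2/4 list 23 higher and the actin-binding list 14 higher. In that fit camera gave adjusted p = 4.4e-26 for ribosome biogenesis, 4.0e-15 for Msn2/4 genes, 2.3e-07 for the endocytic list and 0.00086 for the actin-binding list (limma). With an estimated correlation the adjusted p were 0.32, 0.37, 0.32 and 0.32.

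In the 18-library fit camera called 14 of 32 lists for Sc[Ca] (7 up, 7 down; limma), fry 0 and camera with an estimated correlation 0. Ribosome biogenesis had a median of −0.39 (adjusted p = 4.8e-12, limma and adjusted p = 0.78 with an estimated correlation) and Msn2/4 genes 0.33 (1.4e-06 and adjusted p = 0.80 with an estimated correlation). The actin-binding list was at 0.10 (adjusted p = 0.012, limma and adjusted p = 0.80 with an estimated correlation) and the endocytic list at 0.14 (4.4e-06 and adjusted p = 0.69 with an estimated correlation).

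**Figure D3:**
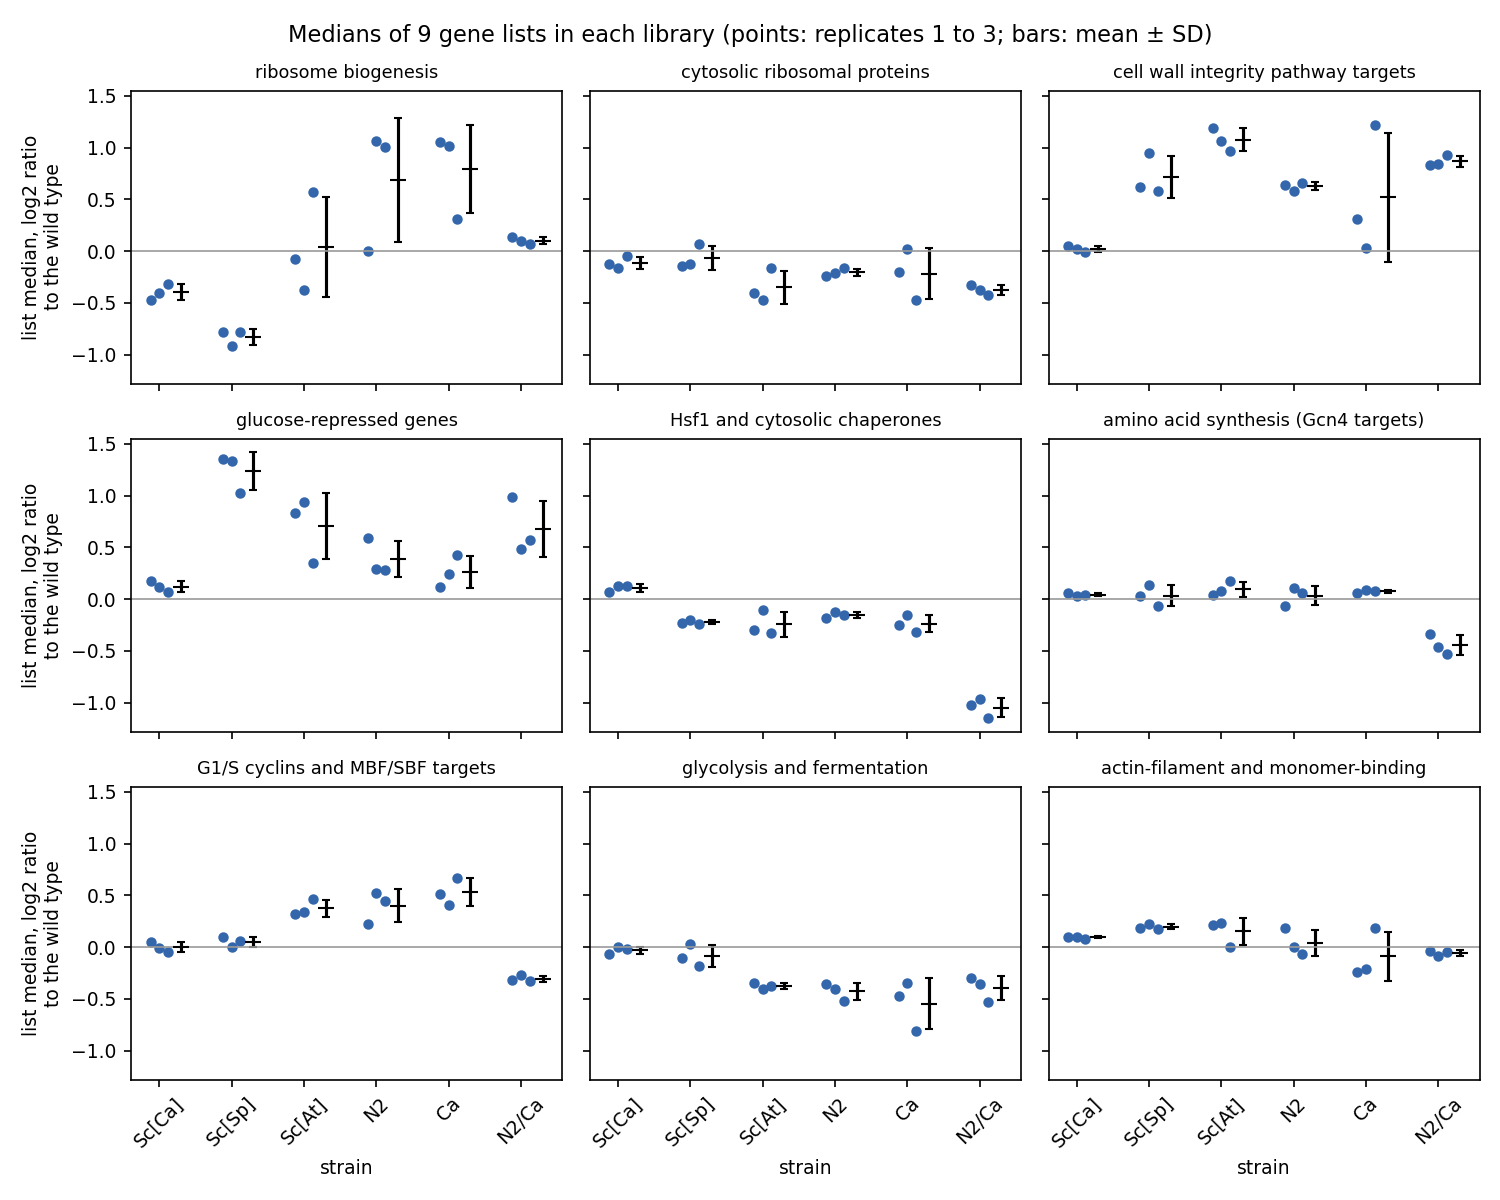
Median log2 difference from the wild type of the members of 9 gene lists. Points are libraries (replicates 1 to 3) and bars the mean ± SD of each strain. Haploid strains are set against ScNI and the diploid N2/Ca against Sc/Sc. Ribosome biogenesis is at −0.79 in Sc[Sp] replicate 1 and 1.06 in Ca replicate 1.

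Sc[Sp] raised 22 of 25 glucose-repressed and 14 of 24 sulfur and methionine genes and lowered 25 of 38 ribosome biogenesis genes. The acetate transporter gene ADY2 rose from 111 ± 17.9 to 486 ± 45.6 (log2 2.13, SE 0.28, limma adjusted p = 0.00040), invertase SUC2 from 2116 ± 151 to 8612 ± 1438 (2.01, SE 0.30, 0.00061) and the lactate permease gene JEN1 by 1.90 (SE 0.38). Among the methionine genes MET6 rose from 1566 ± 241 to 7810 ± 528 (2.33, SE 0.35, limma adjusted p = 0.00076), STR3 by 2.86 (SE 0.47) and MUP1 by 1.81 (SE 0.24). Among ribosome biogenesis genes NOC2 fell from 2439 ± 165 to 1087 ± 88.7 (−1.17, SE 0.27, 0.010, limma adjusted p) and ENP1 by log2 1.14 (SE 0.31). Of the chaperonin that folds actin, 7 of 18 CCT and prefoldin members fell, including CCT6 and CCT5 (both −0.49, SE 0.13 and 0.15) and TCP1 (−0.44, SE 0.12).

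In Sc[Sp] 1217 genes passed, 584 higher and 633 lower (limma, with edgeR 1228, DESeq2 1602, 2149 at unadjusted p below 0.05), with 169 and 50 beyond 2-fold. Leaving out Sc[Sp] replicate 1, 2 or 3 gave 687, 469 and 804, and leaving out ScNI replicate 1, 2 or 3 gave 672, 568 and 438. The fit of the 6 libraries of Sc[Sp] and ScNI gave 2732, and with the N2 and Ca libraries left out of the 18 it was 2417.

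Few actin-binding genes moved in Sc[Sp], and they moved in both directions. LAS17 rose from 776 ± 72.3 to 1253 ± 215 (0.68, SE 0.13, limma adjusted p = 0.0032) and the ring scaffold gene IQG1 by 0.37 (SE 0.12), while ABP140 (−0.42, SE 0.09) and the cable motor gene MYO2 (−0.23, SE 0.08) fell. The list had 2 higher and 2 lower of 34 (1 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.040, limma and adjusted p = 0.55 with an estimated correlation). The Arp2/3 list had 2 higher of 15 (1 alone; ARC19 0.39, SE 0.13) and the endocytic list 3 of 29 (2 alone; YAP1801 0.60, SE 0.19), with camera adjusted p of 0.0035 and 0.019 (limma), and 0.47 and 0.55 with an estimated correlation. Formins, actin cables and polarity had 2 higher and 6 lower of 30 (2 and 6 alone; camera adjusted p = 0.084, limma, and fry 0.024), with GIC2 at 0.85 (SE 0.22), MSB3 at 0.56 (SE 0.16) and PEA2 at −0.49 (SE 0.10). Septins and contractile ring genes rose in 3 of 20, with the primary septum chitin synthase CHS2 at 0.80 (SE 0.14), and tubulins and microtubule proteins had 3 higher and 5 lower of 22 (camera adjusted p = 0.087, limma, and fry 0.045), with BIK1 at −0.49 (SE 0.11).

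Camera called 16 lists in Sc[Sp] (11 up, 5 down; limma), fry 15 and camera with an estimated correlation 0. Glucose-repressed genes rose in 22 of 25 (24 alone, median 1.12, camera adjusted p = 2.0e-16, limma and adjusted p = 0.16 with an estimated correlation). Sulfur and methionine metabolism rose in 14 of 24 (17 alone, 0.58, 1.7e-09 and adjusted p = 0.43 with an estimated correlation). Respiratory chain and TCA cycle genes rose in 22 of 43 (29, with 1 lower, alone, 0.49, 2.2e-09 and adjusted p = 0.47 with an estimated correlation), with SDH1 at 0.93 (SE 0.25). Ribosome biogenesis fell in 25 of 38 (33 alone, −0.86, 2.4e-11 and adjusted p = 0.47 with an estimated correlation). Cell wall integrity targets rose in 9 of 24 (13 alone, 0.71, 3.7e-07 and adjusted p = 0.47 with an estimated correlation), with the mannoprotein gene CWP1 going from 3621 ± 681 to 12631 ± 743 (1.82, SE 0.27). Msn2/4 genes rose in 10 of 26 (17 alone, 0.83, 6.8e-08 and adjusted p = 0.47 with an estimated correlation). G2/M genes rose in 12 of 17 (12 alone, 0.48, 4.7e-08 and adjusted p = 0.43 with an estimated correlation) and DNA damage genes in 4 of 11 (4 alone, 0.19, 0.0040 and adjusted p = 0.43 with an estimated correlation). CCT and prefoldin fell in 7 (10 alone, −0.35, camera adjusted p = 0.0021, limma and adjusted p = 0.47 with an estimated correlation). Hsf1 and cytosolic chaperones fell in 10 of 26 (10 alone, −0.22, 0.0035 and adjusted p = 0.43 with an estimated correlation), with HSP82 at −0.65 (SE 0.15) and YDJ1 at −0.63 (SE 0.17). Pheromone response had 3 higher and 1 lower of 20 (0.41, 0.034 and adjusted p = 0.47 with an estimated correlation), with FAR1 at 0.77 (SE 0.17) and PRM3 at −0.47 (SE 0.15), and libraries at 0.22, 0.72 and 0.12. Histones had 1 lower of 10 (3 alone, −0.33, 0.034 and adjusted p = 0.55 with an estimated correlation). Cytosolic ribosomal proteins had 4 lower of 138 (1 alone, −0.08, 0.040 and adjusted p = 0.79 with an estimated correlation), of which RPP1 (−0.65, SE 0.18) is an RNase P subunit gene taken in by the symbol rule. The libraries were at −0.14, −0.12 and 0.07.

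Lists that camera did not call in Sc[Sp] still held strong genes, and fry called ergosterol synthesis and the markers among them (adjusted p = 0.033 and 0.018, limma). The iron regulon had 4 higher and 5 lower of 23, with the heme oxygenase gene HMX1 at 1.77 (SE 0.27) and the ferroxidase gene FET3 falling from 4228 ± 194 to 1605 ± 38.3 (−1.40, SE 0.25, limma adjusted p = 0.0022). The phosphate regulon rose in 2 of 17, the sodium-phosphate transporter gene PHO89 from 76.9 ± 18.8 to 385 ± 23.6 (2.33, SE 0.56). Ergosterol synthesis fell in 3 of 25 (ERG1 −0.43, SE 0.11), ER folding and unfolded protein response in 2 of 20 (KAR2 −0.31, SE 0.08), and amino acid synthesis had 11 higher and 2 lower of 42 (GCV2 1.96, SE 0.21). Meiosis and sporulation genes rose in 3 of 14 (SPO11 0.91, SE 0.25), haploid-specific genes had 2 higher and 1 lower of 12 (HO −0.66, SE 0.19), and selection and auxotrophy markers 3 higher and 1 lower of 9 (MET17 1.42, SE 0.26). Glycolysis and fermentation, MATa-specific and MATalpha-specific genes had 0 of 17, 7 and 4. For the 2 mating-type lists that count could hardly be otherwise, since every haploid strain mixes both mating types and the main test has no term for them. None of the mitochondrially encoded genes was measured in either table. The drug pump gene PDR5 fell from 31818 ± 4206 to 13652 ± 801 (−1.21, SE 0.17, limma adjusted p = 0.00044), and the kinase gene RCK1 rose most, from 655 ± 290 to 5378 ± 754 (3.11, SE 0.44, 0.00050).

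Sc[At] raised 19 of 24 cell wall integrity targets and lowered 6 of 17 glycolysis and fermentation genes. The glucan synthase gene GSC2 rose from 1324 ± 81.0 to 5775 ± 1237 (log2 2.10, SE 0.54, limma adjusted p = 0.020), the wall protein gene PIR3 from 271 ± 16.4 to 2544 ± 1060 (3.12, SE 0.43, 0.00091) and the kinase homologue gene KDX1 from 422 ± 36.0 to 1832 ± 293 (2.11, SE 0.49, 0.013). The G1 cyclin gene PCL1 rose from 176 ± 8.76 to 688 ± 106 (1.95, SE 0.39, limma adjusted p = 0.0059) and CLN2 by 1.46 (SE 0.34). The glycolytic gene PGK1 fell from 107810 ± 4632 to 67798 ± 6661 (−0.67, SE 0.13, limma adjusted p = 0.0058). Among actin-binding genes VRP1 rose from 1713 ± 84.5 to 3128 ± 453 (0.86, SE 0.23, limma adjusted p = 0.024), LAS17 from 776 ± 72.3 to 1267 ± 93.7 (0.71, SE 0.13, 0.0043), the formin gene BNR1 by 0.49 (SE 0.14) and the ring myosin gene MYO1 by 0.45 (SE 0.11).

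In Sc[At] 886 genes passed, 490 higher and 396 lower (limma, with edgeR 910, DESeq2 1214, 1774 at unadjusted p below 0.05), with 168 and 3 beyond 2-fold. Without Sc[At] replicate 1 the count was 306 and without replicate 2 it was 566, while without ScNI replicate 1, 2 or 3 it was 465, 325 and 391. With the N2 and Ca libraries left out it was 1801.

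Camera called 17 lists in Sc[At] (12 up, 5 down; limma), fry 10 and camera with an estimated correlation 0. Cell wall integrity targets rose in 19 of 24 (21 alone, median 1.11, camera adjusted p = 5.2e-14, limma and adjusted p = 0.30 with an estimated correlation). Ribosomal protein genes fell in 58 of 138 (93 lower and 1 higher alone, −0.35, 3.5e-22 and adjusted p = 0.49 with an estimated correlation), with RPL24B at −0.60 (SE 0.11). Ribosome biogenesis did not move with them: 0 of 38 passed, and the libraries stood at −0.08, −0.38 and 0.57, replicate 3 apart. Glycolysis and fermentation fell in 6 of 17 (12 alone, −0.44, camera adjusted p = 1.6e-05, limma and adjusted p = 0.30 with an estimated correlation), and glucose-repressed genes rose in 12 of 25 (14 alone, 0.65, 2.5e-07 and adjusted p = 0.30 with an estimated correlation). G2/M genes rose in 11 of 17 (12 alone, 0.49, 5.4e-08 and adjusted p = 0.30 with an estimated correlation), with the exit-network kinase gene DBF2 at 0.78 (SE 0.17), and G1/S genes in 9 of 19 (9 alone, 0.36, 9.9e-06 and adjusted p = 0.30 with an estimated correlation). DNA damage genes rose in 4 of 11 (7 higher and 1 lower alone, 0.34, 0.00093 and adjusted p = 0.30 with an estimated correlation), with RNR3 at 1.76 (SE 0.32) and HUG1 at 1.39 (SE 0.16). Hsf1 and cytosolic chaperones had 3 higher and 8 lower of 26 (3 and 10 alone, −0.28, 0.0025 and adjusted p = 0.30 with an estimated correlation): HSP26 rose (1.88, SE 0.43) and SSA2 fell (−0.68, SE 0.17).

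The actin-binding list had 6 higher and 1 lower of 34 in Sc[At] (7 and 2 alone, median 0.16, camera adjusted p = 0.032, limma and adjusted p = 0.61 with an estimated correlation), ABP140 being the lower gene (−0.41, SE 0.09), and libraries at 0.22, 0.24 and −0.00. The Arp2/3 list had 2 higher of 15 (2, with 1 lower, alone, 0.28, camera adjusted p = 0.011, limma and adjusted p = 0.61 with an estimated correlation). CCT and prefoldin had 1 lower of 18, GIM4 (−0.31, SE 0.08; list −0.15, 0.027 and adjusted p = 0.61 with an estimated correlation), and replicate 3 was at −0.02. Septins and contractile ring genes rose in 8 of 20 (8, with 1 lower, alone), with HSL1 at 0.92 (SE 0.19), CHS2 at 0.81 (SE 0.14) and BUD4 at 0.64 (SE 0.11), yet camera did not call the list (adjusted p = 0.11, limma; fry 0.017). The endocytic list had 2 higher of 29 (camera adjusted p = 0.19, limma) and formins, cables and polarity 3 higher, GIC2 at 1.09 (SE 0.22), and 3 lower, SHE3 at −0.50 (SE 0.08). Msn2/4 genes were at 0.59, 1.01 and −0.57 in the 3 Sc[At] libraries, replicate 3 apart again, with 3 of 26 higher (3 alone, 0.28, camera adjusted p = 0.023, limma and adjusted p = 0.75 with an estimated correlation). Phosphate genes had 3 higher of 17 (PHO81 0.61, SE 0.15), pheromone genes 3 of 20 (PRM10 1.22, SE 0.24) and meiosis genes 5 higher and 1 lower of 14 (SPO11 1.16, SE 0.25). Their camera adjusted p were 0.044, 0.018 and 0.022 (limma), and 0.55, 0.55 and 0.61 with an estimated correlation. Histones had 3 lower of 10 (5 alone; HTB2 −0.58, SE 0.17; list −0.34, camera adjusted p = 0.0010, limma and adjusted p = 0.55 with an estimated correlation).

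In N2 13 of 24 cell wall integrity targets rose and 10 of 17 glycolysis and fermentation genes fell, beside the raised chromosomes. The stress protein gene HSP12 (VI) rose from 281 ± 52.1 to 4687 ± 756 (log2 4.06, SE 0.46, limma adjusted p = 6.0e-05), PIR3 from 271 ± 16.4 to 2343 ± 475 (3.09, SE 0.43, 0.00025) and the abundant wall protein gene SED1 from 36289 ± 971 to 88620.0 ± 10350.0 (adjusted p = 0.00015). The glycolytic gene ENO1 fell from 32596 ± 2093 to 18651 ± 2802 (−0.81, SE 0.20, limma adjusted p = 0.0087) and TDH2 by log2 0.76 (SE 0.17). Off the raised chromosomes, the formin gene BNR1 rose from 294 ± 25.7 to 508 ± 102 (0.77, SE 0.14, limma adjusted p = 0.0019) and LAS17 from 776 ± 72.3 to 1076 ± 114 (0.47, SE 0.13, 0.014). The polarity gene GIC2 rose by 1.18 (SE 0.22), while AIM7, an Arp2/3 debranching gene, fell by log2 0.51 (SE 0.14). MYO5 (XIII, 0.83, SE 0.14), AIP1 (XIII, 0.66, SE 0.12) and AIP5 (VI, 0.52, SE 0.16) rose with their chromosomes.

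In N2 1693 genes passed, 961 higher and 732 lower (limma, with edgeR 1751, DESeq2 1979, 2353 at unadjusted p below 0.05), with 226 and 37 beyond 2-fold. Chromosomes VI and XIII, with 10.2% of the tested genes, held 447 or 46.5% of the higher genes, and elsewhere 514 were higher and 731 lower. Without N2 replicate 2 or 3 the count was 843 and 834, and without ScNI replicate 2 or 3 it was 974 and 1111. With N2 replicate 1 and Ca replicate 3 left out it was 2866.

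Camera called 7 lists in N2 (5 up, 2 down; limma), fry 4 and camera with an estimated correlation 0. Ribosome biogenesis rose in 15 of 38 (21 alone, median 0.66, camera adjusted p = 8.9e-06, limma and adjusted p = 0.95 with an estimated correlation), but the libraries stood at 0.00, 1.06 and 1.00, replicate 1 apart. ENP1 rose by 1.08 (SE 0.31) and ERB1 (XIII) by 1.64 (SE 0.44). G1/S genes rose in 9 of 19 (11 alone, 0.42, 2.4e-05 and adjusted p = 0.95 with an estimated correlation), with PCL2 at 1.05 (SE 0.16), RNR1 at 0.95 (SE 0.17) and CLN1 (XIII) at 1.34 (SE 0.14). Glycolysis and fermentation fell in 10 of 17 (10 alone, −0.42, 0.00017 and adjusted p = 0.95 with an estimated correlation), and cell wall integrity targets rose in 13 of 24 (13 alone, 0.61, 0.00047 and adjusted p = 0.95 with an estimated correlation). Glucose-repressed genes had 7 higher and 1 lower of 25 (9 and 1 alone, 0.33, camera adjusted p = 0.026, limma and adjusted p = 0.95 with an estimated correlation), with SUC2 at 1.13 (SE 0.30). G2/M genes had 6 higher of 17 (6 alone, 0.27, 0.010 and adjusted p = 0.95 with an estimated correlation), with CLB2 at 0.57 (SE 0.09). Ribosomal protein genes had 4 higher, among them RPL15B (XIII, 0.93, SE 0.13) and the RNase P gene RPP1 (0.57, SE 0.18), and 16 lower of 138 (1 and 1 alone, −0.20, 2.4e-05 and adjusted p = 0.95 with an estimated correlation).

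The cytoskeletal lists were not called in N2 by camera. Actin-binding genes had 7 higher and 2 lower of 34 (5 and 2 alone, median 0.05, camera adjusted p = 0.70, limma), the Arp2/3 list 2 higher and 1 lower of 15 (0.87) and the endocytic list 1 higher and 2 lower of 29 (0.18), ARK1 at −0.52 (SE 0.13) and RVS161 at −0.38 (SE 0.12). Septins and contractile ring genes rose in 9 of 20 (9, with 1 lower, alone; camera adjusted p = 0.084, limma; fry 0.0082), with GIN4 at 0.58 (SE 0.17), HSL1 at 0.63 (SE 0.19) and HOF1 (XIII) at 0.91 (SE 0.21). Tubulins and microtubule proteins had 6 higher and 4 lower of 22 (camera adjusted p = 0.46, limma). Of these, TUB2 (VI, 0.87, SE 0.24), TUB1 (XIII, 0.71, SE 0.24) and TUB3 (XIII, 0.61, SE 0.17) rose with their chromosomes. CCT and prefoldin had 2 higher, BUD27 (VI, 1.73, SE 0.32) and GIM5 (XIII, 0.72, SE 0.22), and 1 lower of 18, so its median (−0.07) and mean (0.07) differ in sign. The stress genes of Msn2/4 were at 0.79, −0.03 and −0.12 in the 3 N2 libraries, replicate 1 apart. The meiosis and sporulation list, with 0 members on VI and XIII, was not called (3 lower of 14, the same alone, median −0.10, camera adjusted p = 0.24, limma). Its members IME1 and ZIP1 fell, IME1 from 247 ± 18.6 to 111 ± 29.0 (−1.18, SE 0.17, limma adjusted p = 0.00026) and ZIP1 by log2 0.87 (SE 0.14). The DNA damage marker HUG1 (XIII) rose to 343 ± 29.0 from 90.3 ± 10.2 (1.92, SE 0.16, limma adjusted p = 1.2e-05), above the shift of its chromosome.

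Ca resembled N2, and 13 of 17 glycolysis and fermentation genes fell. ENO1 fell from 32596 ± 2093 to 15347 ± 2400 (log2 −1.10, SE 0.20, limma adjusted p = 0.0017), PGK1 from 107810 ± 4632 to 59160.0 ± 13780.0 (−0.89, SE 0.13, 0.00049) and the isocitrate dehydrogenase gene IDH2 from 9754 ± 1351 to 3455 ± 675 (−1.51, SE 0.20, 0.00021). IDH2 fell without its list: of 43 respiratory chain and TCA cycle genes 2 were higher and 4 lower (2 and 3 alone, camera adjusted p = 0.39, limma). The sliding clamp gene POL30 rose from 787 ± 25.4 to 1618 ± 83.7 (1.04, SE 0.12, limma adjusted p = 7.3e-05). BNR1 rose from 294 ± 25.7 to 584 ± 67.8 (0.98, SE 0.14, limma adjusted p = 0.00040), the only actin-binding gene to rise. AIM7 (−0.60, SE 0.14), the tropomyosin gene TPM2 (−0.33, SE 0.09), ABP140 (−0.32, SE 0.09) and the coronin gene CRN1 (−0.29, SE 0.09) fell.

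In Ca 1754 genes passed, 928 higher and 826 lower (limma, with edgeR 1906, DESeq2 2186, 2507 at unadjusted p below 0.05), with 211 and 28 beyond 2-fold. Chromosomes VI and XIII held 309 or 33.3% of the higher genes, and elsewhere 619 were higher and 825 lower. Without Ca replicate 1 the count was 1122, without Ca replicate 3 it was 2682, and without ScNI replicate 1 or 2 it was 1137 and 1048. In the 6 libraries of Ca and ScNI alone it was 741, and with N2 replicate 1 and Ca replicate 3 left out 2952.

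Camera called 6 lists in Ca (3 up, 3 down; limma), fry 6 and camera with an estimated correlation 0. Ribosome biogenesis rose in 19 of 38 (26 alone, median 0.80, camera adjusted p = 4.2e-07, limma and adjusted p = 0.98 with an estimated correlation), with libraries at 1.06, 1.02 and 0.31, replicate 3 apart, and NOG1 at 1.16 (SE 0.30). G1/S genes rose in 14 of 19 (15 alone, 0.53, 1.1e-06 and adjusted p = 0.95 with an estimated correlation), and glycolysis and fermentation fell in 13 of 17 (13, with 1 higher, alone, −0.52, 6.9e-06 and adjusted p = 0.95 with an estimated correlation). The endocytic list fell in 9 of 29 (11 alone, −0.28, 0.00015 and adjusted p = 0.98 with an estimated correlation), with YSC84 going from 1576 ± 54.7 to 931 ± 231 (−0.79, SE 0.23, limma adjusted p = 0.021), RVS161 at −0.52 (SE 0.12) and ARK1 at −0.51 (SE 0.13). Its libraries stood at −0.38, −0.37 and −0.04, so replicate 3, without raised chromosomes, showed almost no fall. Cell wall integrity targets rose in 10 of 24 (10 alone, 0.51, camera adjusted p = 0.0026, limma and adjusted p = 0.98 with an estimated correlation), at 1.22 in replicate 3 against 0.31 and 0.03. Ribosomal protein genes had 3 higher and 19 lower of 138 (2 and 2 alone, −0.22, 6.9e-06 and adjusted p = 0.98 with an estimated correlation), RPP1 again among the higher (0.73, SE 0.18), and its libraries were at −0.21, 0.02 and −0.47.

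Camera called no other cytoskeletal list in Ca. Actin-binding genes had 1 higher and 4 lower of 34 (1 and 4 alone, median −0.12, camera adjusted p = 0.39, limma), and the libraries stood at −0.24, −0.21 and 0.18, replicate 3 apart. The Arp2/3 list moved likewise, −0.41, −0.35 and 0.28, with 2 lower of 15. Formins, cables and polarity had 3 higher and 7 lower of 30, with GIC2 at 0.98 (SE 0.22) and BOI1 at −0.49 (SE 0.06), and septins and contractile ring genes 7 higher and 2 lower of 20, with HSL1 at 0.82 (SE 0.19) and GIN4 at 0.65 (SE 0.17); fry called this list (adjusted p = 0.048, where camera gave 0.29, limma). Hsf1 and cytosolic chaperones had 5 higher and 11 lower of 26 (5 and 11 alone; camera adjusted p = 0.097, limma, and fry 0.039), HSP104 falling from 24934 ± 2424 to 10447 ± 402 (−1.25, SE 0.30). The drug pump gene PDR15 fell from 2976 ± 465 to 624 ± 167 (−2.27, SE 0.37, limma adjusted p = 0.00086).

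**Figure D4:**
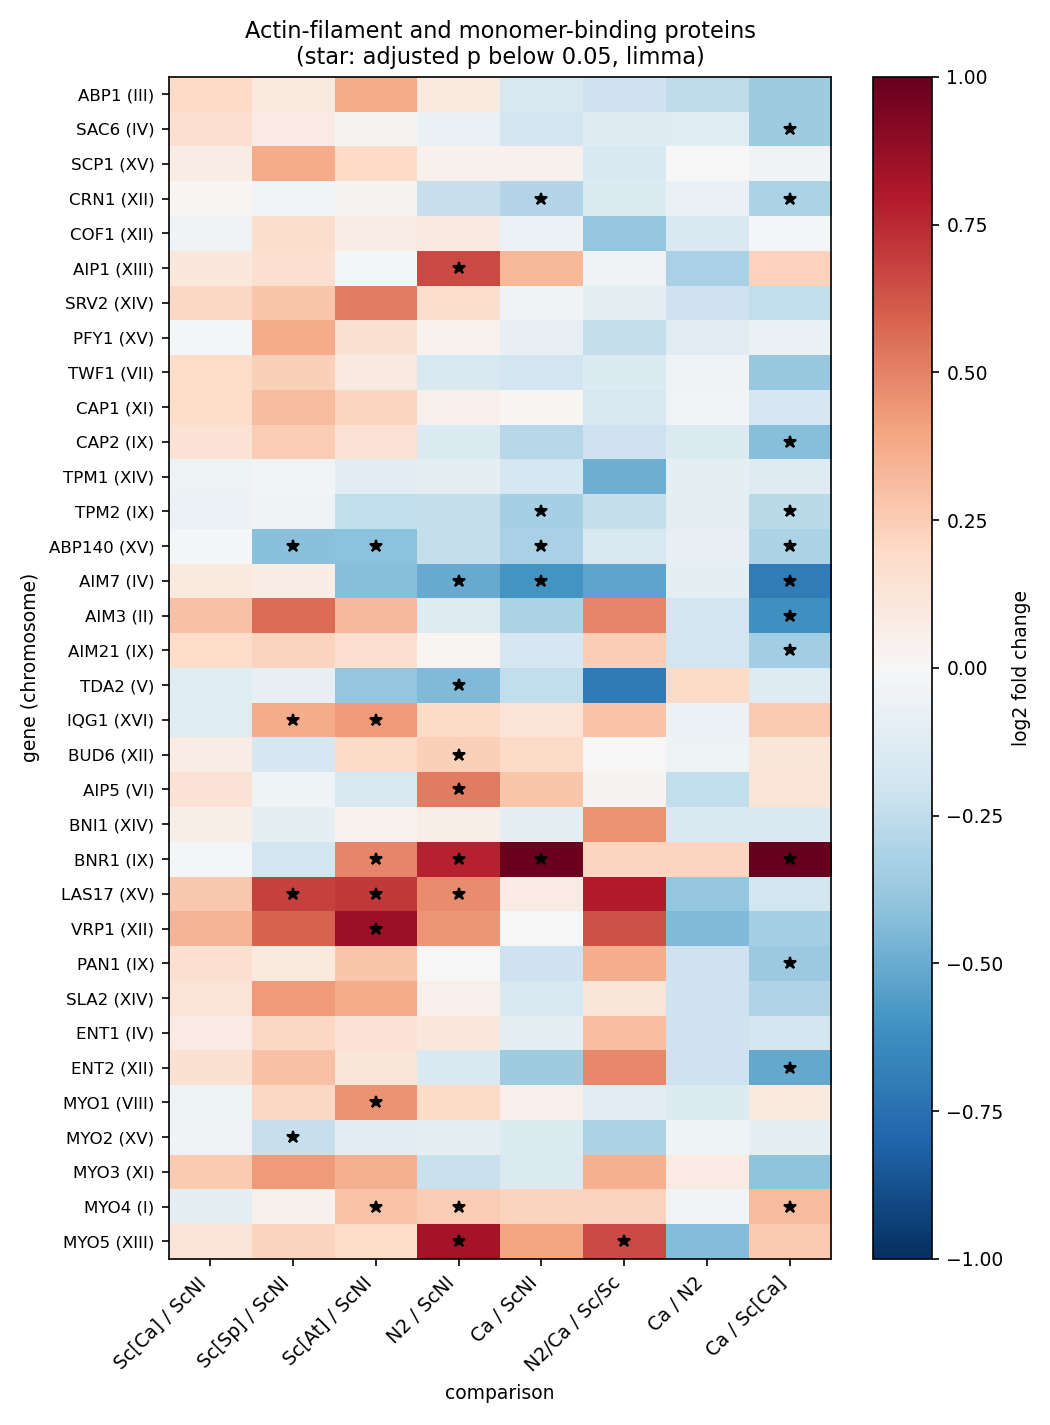
Log2 fold of 34 actin-binding genes (lines, with chromosome) in the 8 comparisons (columns), colour from −1 to 1, with a star where limma adjusted p is below 0.05. The lowest fold is −0.71 and the highest 1.00.

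Ca and N2 differed little from each other. The 3 Ca libraries exceeded the 3 of N2 in PES4 (VI), from 50.1 ± 10.5 to 158 ± 14.0 (log2 1.65, SE 0.16, limma adjusted p = 0.00019) and the chitin deacetylase gene CDA1, from 28.9 ± 6.39 to 82.7 ± 13.3 (SE 0.22, 0.0069). The meiotic cohesin gene REC8 was higher by 1.42 (SE 0.29, limma adjusted p = 0.049) and the inducer gene IME1 by 0.82 (SE 0.17, 0.048). The wall mannoprotein gene TIP1 fell from 12084 ± 2241 to 5611 ± 2522 (−1.19, SE 0.25, 0.048) and SWR1 by log2 0.68 (SE 0.10). ACT1 did not differ by the test (−0.10, SE 0.37, limma adjusted p = 0.97).

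Between Ca and N2 30 genes passed, 24 higher and 6 lower (limma, with edgeR 26, DESeq2 112, 628 at unadjusted p below 0.05). The count hung on the filter, with 3 genes at a mean of at least 100, and on single libraries: 5, 88 and 142 without Ca replicate 1, 2 or 3 and 14, 10 and 12 without N2 replicate 1, 2 or 3. It was 1467 with only replicate 3 of Ca and 53 without Ca replicate 3 and N2 replicate 1. With only these 6 libraries limma passed 0 genes (223 at unadjusted p below 0.05; edgeR 0, DESeq2 25). Camera called 6 lists (1 up, 5 down; limma), fry 0 and camera with an estimated correlation 0. Lower in Ca were Msn2/4 genes (median −0.65, adjusted p = 2.1e-08, limma), the endocytic list (−0.18, 7.5e-05), the actin-binding list (−0.13, 0.0013), G2/M genes (−0.14, 0.0017) and the Arp2/3 list (−0.21, 0.0050), all with 0 members passed and adjusted p = 0.88 with an estimated correlation. Meiosis and sporulation genes were higher (0.43, 1.0e-06, limma and adjusted p = 0.88 with an estimated correlation), with 1 of 14 passed (2 alone), Ca replicate 3 at 0.97 and the other Ca libraries at −0.10 and −0.07. Single libraries stood apart in the lower lists too. Against ScNI the Msn2/4 genes were at 0.79 in N2 replicate 1, −0.03 and −0.12 in the other N2 libraries, and −0.20, −0.40 and −0.17 in Ca. Ca replicate 3 was at 0.28 for the Arp2/3 list, 0.18 for the actin-binding list, 0.45 for G2/M genes and −0.04 for the endocytic list, where Ca replicates 1 and 2 were at −0.41 and −0.35, −0.24 and −0.21, −0.07 and −0.06, and −0.38 and −0.37.

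Ca and Sc[Ca] differed widely. Of 38 ribosome biogenesis genes 34 were higher in Ca, ENP1 by log2 1.67 (548 ± 19.9 to 1786 ± 470, SE 0.31, limma adjusted p = 0.0010) and NOG1 by 1.88 (SE 0.30, 0.00047). Of 29 endocytic genes 20 were lower in Ca, YSC84 from 2026 ± 102 to 931 ± 231 (−1.15, SE 0.23, limma adjusted p = 0.0018) and SYP1 by log2 0.71 (SE 0.13). Actin-binding genes had 2 higher, one of them BNR1 (1.00, SE 0.14, limma adjusted p = 0.00024), and 10 lower, with AIM7 at −0.70 (SE 0.14) and PAN1 at −0.37 (SE 0.10). ACT1 was at 145.9 ± 36.2 in Sc[Ca] and 12798 ± 3629 in Ca (6.43, SE 0.37, limma adjusted p = 1.7e-07). In Ca it stood at 0.886 ± 0.00414 of the introduced gene. Whether these are reads of a native ACT1 or of the introduced gene is open, so the fold is not a measured change of native ACT1.

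In that comparison 2303 genes passed, 1199 higher and 1104 lower (limma, with edgeR 2419, DESeq2 2633, 2837 at unadjusted p below 0.05), with 316 higher and 4 lower on VI and XIII. The fit of those 6 libraries alone passed 1391. Camera called 8 lists (3 up, 5 down; limma), fry 9 and camera with an estimated correlation 0. Ribosome biogenesis (36 higher alone, median 1.13, adjusted p = 1.6e-11, limma), G1/S genes (14 higher of 19, 14 alone, 0.54, 1.7e-05) and cell wall integrity targets (10 higher and 1 lower of 24, the same alone, 0.50, 0.016) were up, with adjusted p = 0.91, 0.84 and 0.91 with an estimated correlation. The endocytic list (20 lower alone, median −0.39, adjusted p = 1.5e-06, limma) and glycolysis and fermentation (13 lower of 17, 13 lower and 1 higher alone, −0.51, 8.5e-05) were down, both at adjusted p = 0.84 with an estimated correlation. Hsf1 and cytosolic chaperones had 2 higher and 11 lower of 26 (the same alone, −0.16, adjusted p = 0.018, limma and adjusted p = 0.84 with an estimated correlation). Msn2/4 genes had 1 higher and 10 lower of 26 (the same alone, −0.73, adjusted p = 0.018, limma and adjusted p = 0.91 with an estimated correlation). The respiratory chain and TCA cycle had 1 higher and 12 lower of 43 (1 and 11 alone, −0.28, adjusted p = 0.016, limma and adjusted p = 0.91 with an estimated correlation), but against ScNI Ca replicate 3 was at 0.34 and the other Ca libraries at −0.18 and −0.30. Ca replicate 3 stood apart likewise in cell wall integrity targets, at 1.22 where replicates 1 and 2 were at 0.31 and 0.03, in the endocytic list, at −0.04 against −0.38 and −0.37, and in ribosome biogenesis, at 0.31 against 1.06 and 1.02. The actin-binding list was not called (2 higher and 9 lower alone, −0.18, adjusted p = 0.090, limma).

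In the diploid N2/Ca 21 of 26 chaperone and 22 of 42 amino acid synthesis genes were lower than in Sc/Sc. Whether N2/Ca or its wild type is the strain that departed cannot be told from this comparison. The chaperone gene BTN2 fell from 12763 ± 2533 to 1074 ± 123 (log2 −3.56, SE 0.16, limma adjusted p = 1.9e-05), the Hsp70 exchange factor gene FES1 by log2 1.97 (SE 0.13) and SSA4 by 1.90 (SE 0.24). LEU1 fell from 20668 ± 3253 to 1847 ± 170 (−3.48, SE 0.14, limma adjusted p = 1.9e-05), BAT1 from 17511 ± 3387 to 3556 ± 330 (−2.29, SE 0.16, 0.00019) and LEU2, also used as a selection marker, from 5521 ± 749 to 1229 ± 261 (−2.18, SE 0.17, 0.00030). The wall gene PRM5 rose from 377 ± 57.2 to 2315 ± 473 (2.61, SE 0.18, limma adjusted p = 0.00019) and the hexose transporter gene HXT4 by 2.42 (SE 0.30). The G1 cyclin gene CLN3 rose from 605 ± 177 to 2203 ± 197 (1.91, SE 0.21, limma adjusted p = 0.0017). The actin-binding list, which leaves out ACT1, held a single changed gene, MYO5 (XIII, 0.66, SE 0.17, limma adjusted p = 0.042).

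In N2/Ca 822 genes passed, 492 higher and 330 lower (limma, with edgeR 878, DESeq2 1344, 1926 at unadjusted p below 0.05), with 150 and 61 beyond 2-fold and 59 higher and 14 lower on VI and XIII. Without N2/Ca replicate 1, 2 or 3 the count was 368, 313 and 266, and without Sc/Sc replicate 2 or 3 it was 489 and 1363. Sc/Sc replicate 3 stood apart from replicates 1 and 2 (chi-square per gene 91.0 and 89.0, against 14.8 between these). N2/Ca replicate 1 stood apart from its replicates 2 and 3 by less (30.5 and 31.5, against 4.96). Camera called 12 lists (7 up, 5 down; limma), fry 10 and camera with an estimated correlation 0. Hsf1 and cytosolic chaperones fell in 21 of 26 (24 alone, camera adjusted p = 7.4e-19, limma), with library medians of −1.03, −0.96 and −1.15. Amino acid synthesis fell in 22 of 42 (27 lower and 3 higher alone, median −0.44, camera adjusted p = 2.0e-11, limma) and ribosomal protein genes in 7 of 138 (1 alone, −0.36, 8.0e-16). Glycolysis and fermentation fell in 3 of 17 (7 alone, −0.42, 0.00065, limma adjusted p) and CCT and prefoldin in 1 of 18 (1 alone, −0.12, 0.045). Each of these 5 lists was at adjusted p = 0.57 with an estimated correlation. Cell wall integrity targets rose in 16 of 24 (18, with 1 lower, alone, median 0.88, camera adjusted p = 1.0e-09, limma) and glucose-repressed genes in 8 of 25 (15 alone, 0.66, 1.3e-06). Pheromone genes rose in 3 of 18 (4 alone, 0.27, 0.0017, limma adjusted p), and the iron regulon in 8 of 22 with 2 lower (9 and 2 alone, 0.43, 0.015). These 4 lists too were at adjusted p = 0.57 with an estimated correlation. Msn2/4 genes had 5 higher and 1 lower of 26 (9 and 1 alone, 0.33, 0.020, limma adjusted p and adjusted p = 0.75 with an estimated correlation), with libraries at 0.69, 0.08 and 0.17, replicate 1 apart. Ribosome biogenesis had 5 higher of 38 (5 alone, 0.10, 0.045 and adjusted p = 0.75 with an estimated correlation) and G2/M genes 2 of 17 (2 alone, 0.15, 0.045 and adjusted p = 0.61 with an estimated correlation). The actin-binding list was not called (1 higher of 34, 0 alone, median −0.07, mean 0.04, adjusted p = 0.89, limma), nor were formins, cables and polarity with 4 higher of 30 (SMY1 0.73, SE 0.11; GIC1 0.95, SE 0.16).

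The calls of the haploid strains overlapped. Of the tested genes 1573 passed in the same direction in at least 2 strains, and 104 were higher and 83 lower in Sc[Sp], Sc[At], N2 and Ca alike; 69 of the 104 lie off VI and XIII. The proline permease gene PUT4 rose by log2 2.79, 1.65, 2.18 and 1.40 in these strains, and the carbonic anhydrase gene NCE103, one of the named genes of N2, by 2.19, 1.96, 2.04 and 1.62. N2 and Ca shared 673 higher and 510 lower genes, where independent lists would share 154 and 104. Off VI and XIII, raised in both, they shared 381 and 510 (independent 61.01 and 116), with a covariance of folds of 0.140 (0.0232 simulated). Sc[Sp] and Sc[At] shared 235 and 144 (independent 49.3 and 43.2), Sc[At] and Ca 287 and 256 (78.3 and 56.3), Sc[At] and N2 257 and 240 (81.1 and 49.9), Sc[Sp] and N2 192 and 135 (96.6 and 79.8), and Sc[Sp] and Ca 165 and 124 (93.3 and 90.0). All strains are compared with the same 3 ScNI libraries, which cannot be split, so part of an excess may come from them, by an amount not measured here. The covariance of folds across genes, which are not independent replicates, was set beside 20 simulations of strains that share only controls. It was 0.187 for N2 and Ca (0.0244 simulated), 0.108 for Sc[Sp] and Sc[At] (0.0255), 0.109 for Sc[At] and Ca (0.0256) and 0.0902 for Sc[At] and N2 (0.0254). For Sc[Sp] it was 0.0242 with N2 (0.0243 simulated) and 0.0104 with Ca (0.0241). For Sc[Ca] it was 0.0466 with Sc[Sp] (0.0246 simulated), 0.0182 with Sc[At] (0.0271), −0.0106 with N2 (0.0249) and −0.0205 with Ca (0.0259). The simulated spread includes differences between replicate numbers and mating types, which cancel between strains of the same make-up. The simulated covariance is therefore too high a mark, and values at or below it leave open whether changes are shared.

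The diploid N2/Ca was set beside the haploids through folds against its own wild type. Across 5723 genes, which are not independent replicates, its folds correlated with those of N2 at 0.293 (Spearman 0.284), Ca at 0.167 (0.172), Sc[Sp] at 0.298 (0.211), Sc[At] at 0.317 (0.296) and Sc[Ca] at −0.0155 (0.0287). Shared calls were 146 higher and 103 lower with N2 (independent lists 81.5 and 42.0), 100 and 86 with Ca (77.4 and 47.4), 149 and 55 with Sc[Sp] (49.2 and 36.3) and 109 and 50 with Sc[At] (39.8 and 22.7). Off VI and XIII, also raised in N2/Ca replicate 1, they were 91 and 102 with N2 (42.7 and 44.8) and 65 and 86 with Ca (50.5 and 50.6), and the folds correlated at 0.275 and 0.135. PIR3 rose in the diploid as in those 4 haploids, from 132 ± 33.3 to 712 ± 161 (log2 2.43, SE 0.22, limma adjusted p = 0.00079).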

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

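The comparisons of Ca with N2 and of Ca with Sc[Ca] were set before the data were examined, and the tests of where the reads of ACT1 come from and the counts over other splits of the libraries were chosen only after the result was seen.

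Ca and N2 were compared directly because each had been set against the same wild type, and 30 genes differed between them (limma; edgeR 26, DESeq2 112). Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest other gave 21. The count was 5, 88 and 142 without Ca replicate 1, 2 or 3 and 14, 10 and 12 without N2 replicate 1, 2 or 3. Ca and Sc[Ca] differed in 2303 genes (limma; edgeR 2419, DESeq2 2633), where 1 of 10 splits gave as many and the highest other gave 0. In either case the splits are too few for a share under 0.05. Whether the difference from Sc[Ca] lies in the actin made or in another difference between the strains was not tested.

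The tables hold entries for introduced actin genes that the comparisons do not use, and each was above its level in the wild type of the same ploidy. The introduced gene was at 21983 in Sc[Ca], 17413 in Sc[Sp], 18930 in Sc[At], 20971 in N2 and 14462 in Ca. In N2/Ca the N2 gene was at 7071 and the Ca gene at 11168. The levels come from tables normalised separately for haploids and diploids.

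ACT1 kept a mean of 13450.0 in N2, 12798 in Ca and 14197 in N2/Ca, while in the other strains with an introduced gene it was below 146. Stretches identical in ACT1 and the introduced genes, sharing reads both ways, are argued against: the N2 or Ca gene of ScNI reached at most 1.26% of its ACT1. A fixed share of each introduced transcript counted at ACT1 stays open as a candidate explanation: the ratios in haploid N2 and Ca predicted ACT1 in the N2/Ca libraries as 15800, 14358 and 13122 against 15859, 13685 and 13048 observed, at most 4.69% off. A native ACT1 gene beside the introduced gene stays open. ACT1 and the introduced gene together were at most 1.10 times the ACT1 of ScNI, divided by the median RNA ratio of chromosome VI. The sum does not show how much of the ACT1 count is native, and all of it could be. A ratio of ACT1 to the introduced gene that is nearly constant over libraries is what the former predicts, but the sequences of the introduced genes, not used here, would be needed to decide.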

How the results depend on the processing

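DESeq2 on recovered reads, chromosome medians subtracted in each library, a mating-type covariate, and the settings that leave out the N2 and Ca libraries, Ca replicates 1 and 2, or Ca replicate 3 and N2 replicate 1 were chosen only after the result was seen. Over 6 haploid and 2 diploid strains, values of the single genes and lists named in the text were counted under the settings fixed in advance. Of these, 11932 were counted as kept, 1317 kept direction but no longer passed, 136 newly passed and 12 moved. Under the settings added later these were 3526, 189 and 50, and 26 that had passed in the main test changed sign. Kept values held direction and side of the threshold, or had not passed in the main test and changed sign. How many were of the latter kind was not counted. Every setting could be run. Depth leaves genes with a mean below 10 untested, and the self-test of Sc[Sp] recovered 34.3% of changes of log2 0.5, so small changes are missed with 3 libraries a strain.

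The lists depend most on the correlation assumed among their genes: with an estimated correlation camera called 0 lists in Sc[Ca], Sc[Sp], Sc[At], N2, Ca, N2/Ca, Ca against N2 and Ca against Sc[Ca] (unadjusted p below 0.05 for 3, 3, 4, 0, 1, 2, 0 and 0). Fry called 0 in Sc[Ca] (3 unadjusted), 10 in Sc[At], 4 in N2 and 0 in Ca against N2 (1 unadjusted). Without Ca replicates 1 and 2 camera called 10 lists in Ca, 10 in Ca against N2 and 15 in Ca against Sc[Ca], and without Ca replicate 3 and N2 replicate 1 it called 11 in Ca against N2. Leaving out each library gave 3 to 13 in Ca against N2.

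Counts of genes moved as follows. In Sc[Ca], DESeq2 gave 2, the fit without the N2 and Ca libraries 4 and the fit of its 6 libraries 961 (456 higher, 505 lower). The 6-library fit gave 2732 in Sc[Sp], 741 in Ca, 1391 in Ca against Sc[Ca] and 0 in Ca against N2 (limma; 223 unadjusted, edgeR 0, DESeq2 25). Without the N2 and Ca libraries the count was 2417 in Sc[Sp] and 1801 in Sc[At]. DESeq2 gave 1344 in N2/Ca and 112 (62 higher, 50 lower) in Ca against N2. A mean of at least 100 left 3 in Ca against N2. Without Ca replicates 1 and 2 it was 1467 (695 higher, 772 lower) in Ca against N2, where the lone Ca library is assumed to vary like the other groups. Without Ca replicate 3 and N2 replicate 1 it was 2866 in N2, 2952 in Ca and 53 (15 higher, 38 lower) in Ca against N2, and the mating-type covariate gave 16 higher and 7 lower there. Leaving out each library gave 438 to 804 in Sc[Sp], 306 to 986 in Sc[At], 834 to 2174 in N2, 1048 to 2682 in Ca, 266 to 1363 in N2/Ca and 5 to 142 in Ca against N2. At adjusted p under 0.01 the genes shared by at least 2 strains were 558. Fewer libraries or a stricter threshold account for part of these by construction, and for the rest the cause was not tested.

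ACT1 newly passed in N2 in the 6-library fit (log2 −0.48, limma adjusted p = 0.044) and with chromosome medians subtracted (−1.21, 0.021), as it did in Ca (−1.12, 0.026), by subtraction of the chromosome VI shift. In N2/Ca it lay between −0.85 and −0.69 when each library was left out, no longer passing without N2/Ca replicate 2 (−0.74, adjusted p = 0.052, limma) or 3 (−0.71, 0.050).

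With the replicate block, the same-numbered pairing being used, no count moved beyond 1.5-fold: Sc[Ca] 1, Sc[Sp] 1099, Sc[At] 737, N2 1617, Ca 1659, N2/Ca 882, Ca against N2 20 and Ca against Sc[Ca] 2218.

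Sign changes of values that had passed in the main test came with chromosome medians subtracted, by that construction. They also came with Ca replicates 1 and 2 left out, which leaves the library without raised chromosomes. With chromosome medians subtracted N2 had AIP1 −0.12, AIP5 −0.21, GIM5 −0.0553, TUB1 −0.0718, TUB3 −0.17, PHO84 −0.00326, GCV2 −0.00742, HAC1 −0.0190, KAR5 −0.0994, CIK1 −0.17 and DDR48 −0.0834, Ca had TUB3 −0.12, and Ca against Sc[Ca] had TUB3 −0.0732 and RPL15B −0.14. With Ca replicates 1 and 2 left out Ca had GIM5 −0.0432, CIN4 −0.14, RPL29 −0.14, HXT2 −0.16 and HMG1 −0.0866, and Ca against Sc[Ca] had RPL29 −0.13, HMG1 −0.025 and the respiratory list 0.19. Ca against N2 then had the actin-binding list at 0.16, the Arp2/3 list at 0.25, the endocytic list at 0.0766 and the G2/M list at 0.11. For the lists the cause was not tested.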

Other observations

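The group of proteasome genes and the tests of the chromosomes, of the ribosome biogenesis genes and of the splits were chosen only after the result was seen.

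Between 12 and 21 of 33 proteasome subunit genes fell in each of 4 haploid strains where RPN4, the gene of their transcription activator, was higher. The group, formed and named after its values were seen, held 33 genes. Of these 12 fell in Sc[Sp], 18 in Sc[At], 15 in N2 with 4 higher, and 21 in Ca (limma). Their medians were log2 −0.16, −0.29, −0.22 and −0.26. PRE3, PUP2, RPN3, RPN6, RPN9, RPT2, RPT5, RPT6 and SCL1 fell in these 4 strains alike, 9 of 33. RPN4 itself rose by 0.64, 0.64, 0.93 and 0.70 (SE 0.08 each; limma adjusted p = 0.00035, 0.00050, 1.6e-05 and 0.00010). In the diploid N2/Ca the median was −0.24 with 0 passed (limma; 14 lower at unadjusted p below 0.05), and RPN4 fell by log2 0.59 (SE 0.12, adjusted p = 0.015, limma). A group formed from its values cannot be tested on them, and the strains share their wild type.

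Chromosomes VI and XIII were raised in 5 of 6 N2 and Ca libraries. The authors' normalisation, a single factor per library, moves all chromosomes alike. It cancels in these medians, which are taken against the genes of the other chromosomes. That the other 13 chromosomes (XI left out) lay at most 0.18 from 0 in those libraries is therefore no test of it. GC content or gene length is argued against: against 20 matched genes of other chromosomes each, the lowest strain mean of VI or XIII was still 0.65 (Ca, VI), and N2 kept 0.80 and 0.84. Extra copies of whole chromosomes are a candidate explanation: the lowest mean of a 100 kb bin was 0.54, so both chromosomes were raised along their length (N2 0.68 to 0.86, Ca 0.54 to 0.70). The values near 0.9 lie close to a doubled copy number and those near 0.5 may reflect a mixed culture or a diploid with 3 copies, which only DNA of the same cultures could show.

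The ribosome biogenesis list had a median of 0.66 in N2 and 0.80 in Ca, with 15 and 19 of 38 members higher (limma). Camera called it, but not with an estimated correlation (adjusted p = 0.95 and 0.98, limma). Members on VI and XIII are argued against as the whole cause, since the 34 members elsewhere had a median of 0.63 in N2 and 0.75 in Ca. With TMM factors the lower median was still 0.65, so the choice between these factors did not make the rise. TMM also takes most genes as unchanged, so a shift of most genes stays untested. The state of single libraries cannot be told apart from an effect of the actin: Ca replicate 3, with VI and XIII at 0.06 and −0.00, stood at 0.31, and N2 replicate 1, with both raised by 0.51 and 0.54, stood at 0.00. The other 4 libraries, with both raised by 0.89 to 0.98, were at 1.00 to 1.06. N2/Ca replicate 1, with both raised by 0.44 and 0.49, was at 0.14 beside 0.09 and 0.07 in the other N2/Ca libraries. Raised chromosomes thus came without a rise of these genes in N2 replicate 1, but with so few libraries extra chromosomes and the actin cannot be parted, and no biological explanation was tested.

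Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In Sc[Ca], Sc[Sp], Sc[At], N2, Ca and N2/Ca 1 split gave as many genes, the real one, with 1, 1217, 886, 1693, 1754 and 822 genes, and the highest other gave 0 (limma). For Sc[Ca], Sc[Sp], Sc[At] and N2, splits that part the same-numbered pairs with ScNI and splits that do not gave 0 alike. The fit of the 6 Sc[Ca] and ScNI libraries gave 961 genes, with 11 in the highest other split and 1 split as high. For the F test over 18 libraries 1 of 100 regroupings, the real one, reached 3517 genes and the highest other 1250. These regroupings mix replicate numbers and mating types. With strains shuffled only among libraries of the same replicate number, the mating-type make-up of each group is kept. There 1 of 100 regroupings reached 3517, again the real one, and the highest other gave 1405. The share is under 0.05, which argues against chance but does not show which difference between the strains counts.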
